A study of Mus musculus with 35 samples.

How the data were processed

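Total RNA of 35 mouse aortas was sequenced, 1 library per animal, in 12 groups defined by genotype, diet and weeks on diet as the library titles give them. Per the labels, aortas were taken from the root to the iliac bifurcation after perfusion, with the fat around the vessel removed. In WT WD 22 weeks replicate 3 the genotype tag named EKO and the title WT. The library was kept as WT before the data were examined, and its Apoe level was 540.4.

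The authors deposited 1 table with a column of normalised signal per library, the columns adding to between 907500 and 1137700. The values look like estimated read counts divided by a factor per library to a similar total. That was inferred from the values and not read from a label. The submitters' notes name Bowtie 0.12.2, Bowtie2 and RSEM and the genome builds mm8 and mm9, with no role or order. Counting, the removal of low genes and the kind of size factor are not stated. Of the values at or below 1.5, between 71.6 and 82.1% in each library lay within 0.02 reads of a whole number of reads, so whole read counts could not be recovered and tools that need counts (edgeR, DESeq2) were not used. The step between low values gave the reads behind each library, 6850000 to 25330000, with 18 to 222 genes at 0 in a library. The 10 highest genes took 5.62 to 11.22% of the signal. Genes are given by symbol alone, so no genome positions are given. In the mouse annotation (GRCm38), 13836 symbols were found by name and 300 as a synonym, 23 had been turned into dates and 2 occurred more than once. Genes whose reads are shared with near-identical copies cannot be told apart in such a table.

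Differences were tested with limma 3.58.1 in R 4.3.3 (robust, with an intensity trend) on log2(value + 1) in 1 fit of all 12 groups without covariates, over 14157 genes with a value of at least 1 in at least 3 libraries (17 removed). Adjusted p is Benjamini-Hochberg within a comparison, with a threshold of 0.05, and all tests are two-sided except Fisher's exact test of chromosomes, which is one-sided. There were 20 comparisons of 2 groups and 3 interactions, fixed before the data were examined, and 1 more (EKO/hA-I against WT on WD at 22 weeks) was added after they had been examined. The tissue terms, the sex term, rescaling and the omission of libraries with high nerve genes were also chosen after seeing the data.

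A total of 38 gene lists with 695 members, 666 of them measured, were fixed before the data were examined. They cover cell types of the aorta and its surroundings, pathways of lipid, lysosome, immune, matrix and energy metabolism, and signs of RNA or tissue handling. Each of the 37 lists with enough measured members was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list moves one way without comparing it with other genes. Calls that held with an estimated correlation were 7 in EKO against WT on WD at 22 weeks, 2 in EKO/hA-I against EKO on WD at 22 weeks, 2 in WD against chow in EKO at 22 weeks, 2 in 22 against 6 weeks in EKO on WD and 2 in the interaction of genotype and duration on WD. In the other comparisons 0 held. Members were also counted over all genes and adjusted over the list alone. Lists can share members, and the lysosome and sphingolipid lists both hold Glb1, so calls of such lists are not independent of each other.

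Genes were named by a rule fixed before the data were examined. It takes Apoe and Apoa1, then, among genes that passed, had ranges apart and a mean log2 value of at least 1, up to 8 rises and 8 falls of largest size in 3 comparisons at 22 weeks (EKO against WT and EKO/hA-I against EKO on WD, WD against chow in EKO) and up to 3 of each elsewhere, and up to 4 members of smallest p from each list described. Predicted genes and receptor segments were counted without being named. Most genes of this rule that lost the call when 1 library was left out are not described. Gene functions in the text are background.

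Alternatives planned before the data were examined were a fit of the compared groups alone, a replicate block from the numbers in the titles, pseudocounts of 0.1 and 5, no filter, each library left out in turn, and, for lists, the estimated correlation and fry. Alternatives added later were terms for brown fat, for brown fat and skeletal muscle, and for these with nerve and cardiac muscle (called the 4 tissue terms, each the mean of a marker list), a term for libraries without Y-linked transcripts, median-ratio rescaling (factors 0.973 to 1.022) and the omission of the 2 libraries with the highest nerve genes. Whether the replicate numbers of the titles pair animals was checked by the correlation of residuals within pairs. Of 21 comparisons of 2 groups, 3 had every pair above 0.1, all of them 22 against 6 weeks: WT on WD (0.13 to 0.34), EKO on WD (0.12 to 0.44) and, with 2 pairs only, EKO/hA-I on chow (0.28 to 0.35). No label states a pairing, but the numbers go with sex, since 9 of the 12 libraries without Y-linked transcripts are replicate 1, 3 are replicate 2 and 0 are replicate 3.

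The procedure was tested on simulated data with noise drawn independently for each gene. A log2 change of size 1 was made in 100 genes and of size 2 in another 100. For EKO against WT on WD at 22 weeks, 71% of genes changed by 1 and 93% of genes changed by 2 were recovered, with 7 false calls. Independent noise lacks the correlation between genes of real libraries. With residuals of the real libraries and no group effect, 100 simulations called up to 432 genes in this comparison (median 0). For EKO/hA-I against EKO on chow at 6 weeks the shares recovered were 58% and 89%, with 7 false calls. In both comparisons camera found the lysosome list, which had been shifted, and 0 of the other lists counted. The macrophage, foam cell, sphingolipid and matrix protease lists were left out of that count. Overlap between comparisons was set against 100 simulations that kept the shared libraries and held no group effect. Its counts by list were also taken without EKO/hA-I WD 22 weeks replicate 2, a step chosen after seeing the data. Other splits of the same libraries were fitted in place of each comparison of groups with 3 libraries. Figures were drawn with matplotlib 3.10.9.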

Results

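RNA from 35 mouse aortas was sequenced, 1 library per aorta, in 12 groups formed by 3 genotypes, 2 diets and 2 durations. The genotypes were wild type (WT), mice lacking apolipoprotein E (EKO), a ligand through which the liver clears remnant lipoproteins, and EKO mice with a surplus of human apoA-I (EKO/hA-I), the main protein of high-density lipoprotein. Mice aged 8 weeks at the start received chow or a Western diet (WD) for 6 or 22 weeks. Each group held 3 libraries except EKO/hA-I on chow for 6 weeks, which held 2. Between 6850000 and 25330000 reads stood behind a library (median 15050000), as inferred from the smallest step between its values. The table gave normalised read counts, 14157 genes were tested, and values in the text are group means ± SD on that scale. Differences are log2 fold changes ± SE of value plus 1, with n = 3 in each group unless stated and adjusted p from limma. These p-values measure only the spread between these samples.

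Apoe ranged from 416 to 1276 in the 12 WT libraries and from 5.37 to 29.7 in the other 23, so it parted WT from the rest as the titles do. It does not separate EKO from EKO/hA-I and so cannot check those titles. Mouse Apoa1 stayed between 0 and 7.64, and the human transgene was not analysed here because the table holds mouse genes. Y-linked transcripts were missing from 12 libraries (mean of 4 genes at most 1.33, against at least 38.2 in the others). Those 12 libraries comprised 1 in each of 10 groups, 2 of EKO on chow for 22 weeks and 0 of EKO/hA-I on chow for 22 weeks. Markers of neighbouring tissue varied widely between libraries. Ucp1, the thermogenic protein of brown fat, ranged from 603 to 9750.3, and Acta1, skeletal muscle actin, from 1.013 to 766.7. Myh6, a cardiac myosin, reached 3658 in WT chow 22 weeks replicate 1, while Th, the rate-limiting enzyme of catecholamine synthesis, reached 249 in EKO chow 6 weeks replicate 1 and 319 in EKO/hA-I chow 6 weeks replicate 2. Across genes, libraries of one group correlated with a median r of 0.968 and libraries of different groups with 0.949, genes not being independent replicates.

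**Figure D1:**
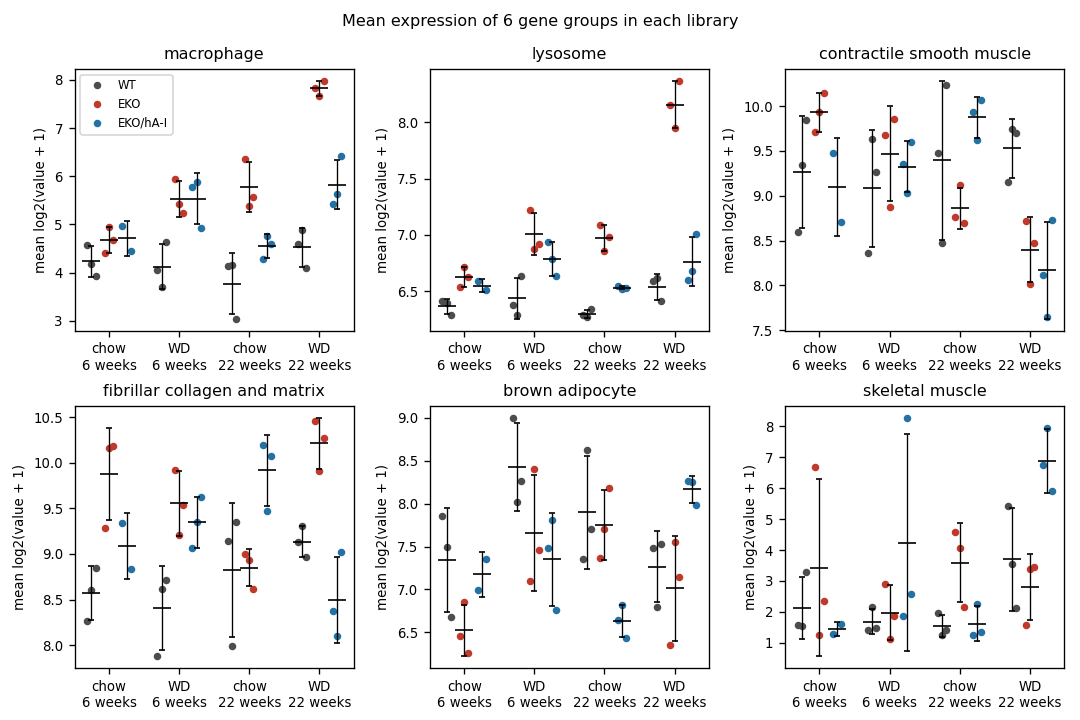
Mean log2(value + 1) of 6 marker gene groups in each library (points), with the group mean and SD (bars), by diet and weeks on diet for WT, EKO and EKO/hA-I. Macrophage genes average 7.83 and lysosome genes 8.15 in EKO after 22 weeks of WD, above every other group, and skeletal muscle genes average 6.88 in EKO/hA-I after 22 weeks of WD.

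How apoE deficiency changed the aorta was asked first after the longest WD feeding. At 22 weeks of WD, genes of lipid-loaded macrophages were far higher in EKO than in WT aortas (n = 3 against 3). Spp1, which encodes the matrix glycoprotein osteopontin, averaged 9604 ± 2323 against 97.9 ± 133 (log2 fold change 8.06 ± 1.24, adjusted p = 1.7e-05, limma). Cd5l, a scavenger-receptor family protein secreted by macrophages, averaged 1585 ± 496 against 16.9 ± 20.1 (7.11 ± 1.05, adjusted p = 1e-05). Mmp12, the macrophage elastase, averaged 838 ± 168 against 11.1 ± 12.8 (6.79 ± 0.81, adjusted p = 4.1e-07), and Gpnmb, a glycoprotein of lysosome-rich macrophages, averaged 5464 ± 2153 against 71 ± 56.7 (6.46 ± 0.77, adjusted p = 4.2e-07). Log2 fold changes of 6.35 ± 0.69 for the proton pump subunit Atp6v0d2, 6.24 ± 0.56 for the integrin Itgax (CD11c), 5.76 ± 0.41 for the hyaluronan-degrading Cemip and 5.62 ± 0.49 for galectin-3 (Lgals3) completed the 8 largest rises. Among the lowered genes, Apoe itself changed by -4.79 ± 0.31 (adjusted p = 8.8e-11), the hedgehog antagonist Hhip by -2.84 ± 0.48 (3.16 ± 0.86 against 29.7 ± 12), leptin (Lep) by -2.67 ± 0.63 (10.5 ± 4.35 against 69.8 ± 14.8) and the netrin receptor Unc5c by -2.30 ± 0.39 (11.9 ± 4.19 against 62.1 ± 18.6).

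Fixed gene lists put these changes into groups. Of the macrophage markers 17 of 18 rose (17 adjusted over the list alone; adjusted p = 0.0475 with an estimated correlation). Cd68 averaged 448 ± 124 against 16 ± 7.28 and the modified-lipoprotein receptor Msr1 116 ± 18.7 against 4.28 ± 1.44. Foam cell genes rose in 14 of 18 cases (16 adjusted over the list alone; adjusted p = 0.0208 with an estimated correlation), with Soat1, which esterifies cholesterol for storage, at 2.48 ± 0.26. LXR targets, the genes that answer to excess sterol, rose in 10 of 13 cases (10 adjusted over the list alone; adjusted p = 0.034 with an estimated correlation). The cholesterol exporter Abcg1 averaged 405 ± 73.8 against 23.5 ± 6.15. Lysosome genes rose in 43 of 49 cases (45 adjusted over the list alone) with a median of 1.26 and adjusted p = 0.00751 with an estimated correlation. The protease Ctsl averaged 3818 ± 1346 against 334 ± 74.9, the glycosidase Gla 72.5 ± 15.2 against 9.82 ± 0.329 and the glucuronidase Gusb 505 ± 70.1 against 66.2 ± 3.88. Sphingolipid genes rose in 21 of 47 cases and fell in 0 (24 adjusted over the list alone; adjusted p = 0.00438 with an estimated correlation). Their risen members included the activator protein Psap at 2.23 ± 0.19 and the lysosomal enzyme Hexa at 1.96 ± 0.18, both of glycolipid breakdown. The lysosome and sphingolipid lists both hold Glb1, so here and below their calls are not independent. Cytokine, chemokine and adhesion genes rose in 31 of 35 cases (32 adjusted over the list alone; adjusted p = 0.0249 with an estimated correlation). The endothelial adhesion molecule Vcam1 averaged 538 ± 41.3 against 58.7 ± 15.5 and the chemokine Cxcl16 206 ± 15.3 against 15.8 ± 3.73. Matrix proteases and inhibitors rose in 14 of 21 cases (15 adjusted over the list alone; adjusted p = 0.034 with an estimated correlation). Adam8 averaged 216 ± 18.4 against 4.49 ± 1.89 and the collagenase Mmp13 56.1 ± 14.1 against 0.907 ± 0.502.

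Genes of the vessel wall moved as well. Modulated smooth muscle and cartilage genes rose in 12 of 16 cases and fell in 1 (13 adjusted over the list alone; adjusted p = 0.123 with an estimated correlation). The cartilage collagen Col2a1 averaged 36.1 ± 16.6 against 0.367 ± 0.274 and Timp1 184 ± 19 against 13.6 ± 4.57. Contractile smooth muscle genes fell in 7 of 16 cases (12 adjusted over the list alone; adjusted p = 0.587 with an estimated correlation). The actin-binding Synpo2 averaged 137 ± 60.9 against 467 ± 105 and the integrin Itga8 612 ± 271 against 2004 ± 406. Collagen and matrix genes rose in 8 of 21 cases (9 adjusted over the list alone; adjusted p = 0.671 with an estimated correlation), with Thbs1 at 1147 ± 279.7 against 41.5 ± 18.4. MHC class II genes rose in 7 of 11 cases (7 adjusted over the list alone; adjusted p = 0.613 with an estimated correlation). H2-Ab1 differed by 2.15 ± 0.39. In all, 3114 of 14157 genes passed, 2095 higher and 1019 lower in EKO. Over all tested genes, the ranges of the 2 groups did not overlap for 40.5%, and chance gives 10%. Of 37 lists tested, 17 were called with a preset correlation and 7 also with an estimated one. Brown adipocyte and skeletal muscle markers had medians of -0.52 and -0.94 between these groups without a call (adjusted p = 0.831 with an estimated correlation and 0.905).

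On chow for 22 weeks, EKO aortas already carried more macrophage and complement transcripts than WT aortas (n = 3 against 3). Cd5l averaged 314 ± 60.6 against 2.52 ± 2.38 (6.71 ± 1.05, adjusted p = 0.00018, limma), Gpnmb 480.3 ± 77.9 against 24.2 ± 12.5 (4.39 ± 0.77) and Mmp12 82.1 ± 17.2 against 4.57 ± 2.96 (4.05 ± 0.81, adjusted p = 0.0017). Apoe was lower by -5.19 ± 0.31. Macrophage markers rose in 16 of 18 cases (17 adjusted over the list alone; adjusted p = 0.142 with an estimated correlation). The complement subunit C1qb averaged 165 ± 72.5 against 29.1 ± 10.8. Complement genes rose in 13 of 16 cases (15 adjusted over the list alone; adjusted p = 0.142 with an estimated correlation). Factor B (Cfb) differed by 2.02 ± 0.31. MHC class II genes rose in 7 of 11 cases (8 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation). H2-Ab1 differed by 2.20 ± 0.39. Lysosome genes rose in 26 of 49 cases (31 adjusted over the list alone; adjusted p = 0.146 with an estimated correlation). The fucosidase Fuca1 differed by 0.79 ± 0.13, and the membrane glycoprotein Cd68 averaged 65.7 ± 18.5 against 8.87 ± 4.25. Erythroid genes rose in 7 of 9 cases (7 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation). The haem synthesis enzyme Alas2 differed by 2.38 ± 0.56. Cardiac muscle genes fell in 5 of 12 (8 adjusted over the list alone; adjusted p = 0.439 with an estimated correlation), the Myh6 level of WT replicate 1 being 3658. Adjusted p passed for 2165 genes, 1041 higher and 1124 lower (ranges apart for 25.3% of all genes, 10% by chance). The count fell to 745 without EKO replicate 1 and to 11 when the fit held only these 6 libraries. It was 3527, 2857 and 1935 with brown fat, with brown fat and skeletal muscle, and with all 4 tissue terms. The smaller fit kept the calls of Cd5l, Gpnmb, Mmp12 and Apoe and ended those of C1qb, Cd68, Cfb, Fuca1, H2-Ab1 and Alas2, the last ended also by 4 tissue terms.

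After 6 weeks the genotypes differed in fewer genes. On chow, besides Apoe (8.99 ± 3.19 against 1009 ± 294; -6.67 ± 0.31, adjusted p = 6.3e-14, limma), the microfibril-binding Adamtsl2 averaged 56.5 ± 14.7 against 6.08 ± 1.68 in EKO against WT (3.01 ± 0.48, adjusted p = 0.0021) and Apoc1, the apolipoprotein gene next to Apoe, 6.55 ± 1.98 against 80.6 ± 43.2 (-3.30 ± 0.48). Collagen and matrix genes rose in 10 of 21 cases (21 adjusted over the list alone; adjusted p = 0.465 with an estimated correlation). The collagen-binding Sparc averaged 4094 ± 992 against 1684 ± 204 (1.26 ± 0.25), whose adjusted p was 0.1 without WT replicate 1 and 0.094 without EKO replicate 3. Mitochondrial respiration genes fell in 11 of 27 cases (24 adjusted over the list alone; adjusted p = 0.465 with an estimated correlation), and brown adipocyte genes in 2 of 12 (5 adjusted over the list alone; adjusted p = 0.534 with an estimated correlation), brown fat markers moving with this group. In total 704 genes passed (321 higher, 383 lower; ranges apart for 27.1% of all genes, 10% by chance). This count was 16, 84 and 1533 without WT replicates 1, 2 and 3, 1185, 160 and 21 without EKO replicates 1, 2 and 3, 9 in a fit of these 6 libraries alone, which ended the calls of Apoc1 and Sparc, 1094 without the 2 libraries of highest nerve genes (EKO replicate 1 and another in EKO/hA-I) and 122 with a brown fat term.

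On WD for 6 weeks, EKO aortas differed from WT mostly by higher expression, in 558 of 770 genes (ranges apart for 24.9% of all genes, 10% by chance). Apoe averaged 14.5 ± 2.37 against 556 ± 224 (-5.11 ± 0.31, adjusted p = 3.9e-11, limma). The epithelial lectin Lgals4 averaged 7.21 ± 1.62 against 31.2 ± 5.21 (-1.98 ± 0.29, adjusted p = 0.00071). Macrophage markers rose in 10 of 18 cases (16 adjusted over the list alone; adjusted p = 0.203 with an estimated correlation). The growth factor receptor Csf1r averaged 106 ± 15.8 against 39.1 ± 12.1 (1.45 ± 0.28), whose adjusted p was 0.051 without WT replicate 1 and 0.052 without EKO replicate 1. Adventitial fibroblast genes rose in 10 of 12 cases (12 adjusted over the list alone; adjusted p = 0.155 with an estimated correlation). The stromal marker Cd248 differed by 1.74 ± 0.29. Complement genes rose in 9 of 16 cases (13 adjusted over the list alone; adjusted p = 0.155 with an estimated correlation). Cfb differed by 1.79 ± 0.31 and the inhibitor Serping1 by 1.49 ± 0.26. Lysosome genes rose in 19 of 49 cases (31 adjusted over the list alone; adjusted p = 0.155 with an estimated correlation). Fuca1 differed by 0.68 ± 0.13. The total was 73 and 358 without WT replicates 1 and 2, 63 and 433 without EKO replicates 1 and 3, 1 in a fit of these 6 libraries, which of the genes named here kept Apoe alone, and 277 with a brown fat term. Brown adipocyte genes had a median of -0.77 between the groups (adjusted p = 0.532 with an estimated correlation), with a preset-correlation call lost without EKO replicate 1 (adjusted p = 0.0613).

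**Figure D2:**
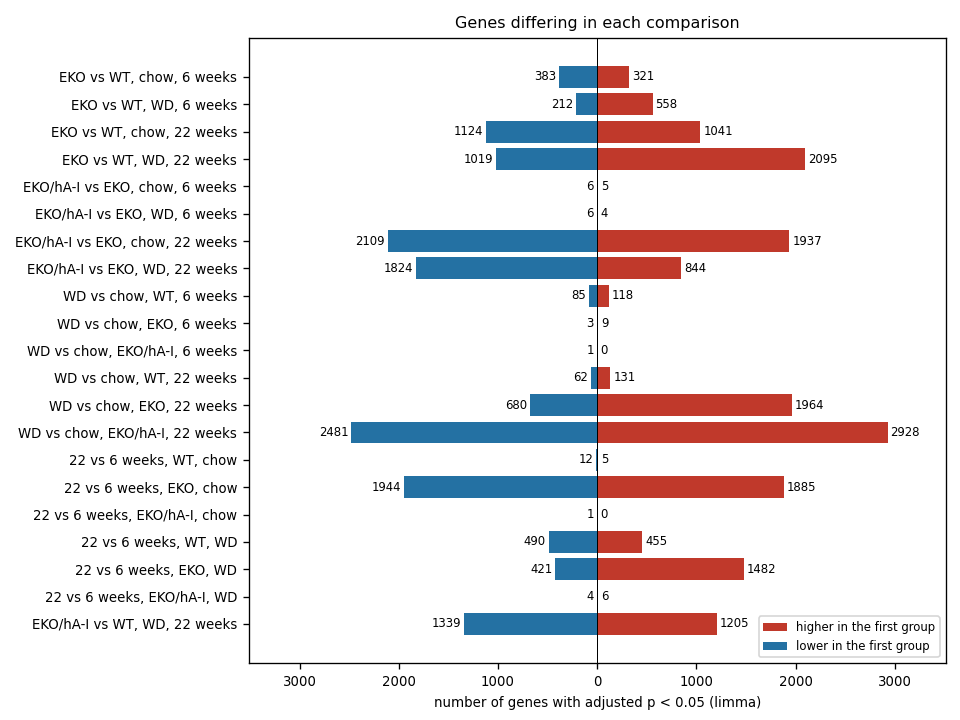
Number of genes with adjusted p under 0.05 (limma) that were higher (right) or lower (left) in the first group of each of 21 comparisons. The largest count is 5409, between diets in EKO/hA-I at 22 weeks, and the smallest is 1, in 2 comparisons that include EKO/hA-I on chow for 6 weeks.

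What human apoA-I changed in EKO aortas was asked next. After 22 weeks of WD, genes of lipid-loaded macrophages were lower in EKO/hA-I than in EKO (n = 3 against 3). Cd5l averaged 26.6 ± 20.2 against 1585 ± 496 (-6.34 ± 1.05, adjusted p = 8.4e-05, limma), Mmp12 27.8 ± 23.9 against 838 ± 168 (-5.40 ± 0.81, adjusted p = 2.5e-05) and Gpnmb 208 ± 142 against 5464 ± 2153 (-5.00 ± 0.77, adjusted p = 3.5e-05). Spp1 averaged 320.2 ± 315 against 9604 ± 2323 (-5.68 ± 1.24, adjusted p = 0.0018), a call that ended with brown fat and skeletal muscle terms. Trem2, a lipid-sensing receptor of macrophages, averaged 14.6 ± 12.5 against 238 ± 57.8 (-4.28 ± 0.60), and Atp6v0d2, Cemip and Itgax changed by -5.27 ± 0.69, -4.75 ± 0.41 and -4.34 ± 0.56. The 8 genes with the largest rises under the naming rule belong to skeletal muscle, such as the fast myosin Myh1 at 264 ± 193 against 5.12 ± 6.4 (5.52 ± 1.58). Without EKO replicate 1 and without EKO/hA-I replicates 1 and 2 the adjusted p of Myh1 was 0.075, 0.061 and 0.068.

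By list, lysosome genes fell in 41 of 49 cases (41 adjusted over the list alone; adjusted p = 0.0134 with an estimated correlation). Ctsl averaged 344 ± 71.8 against 3818 ± 1346, Gla 10.1 ± 3.3 against 72.5 ± 15.2 and Gusb 90.5 ± 25.8 against 505 ± 70.1. Sphingolipid genes fell in 20 of 47 cases and rose in 3 (22 adjusted over the list alone; adjusted p = 0.0134 with an estimated correlation). The ceramidase Asah1 differed by -1.54 ± 0.14. Macrophage markers fell in 16 of 18 cases and rose in 1 (17 adjusted over the list alone; adjusted p = 0.222 with an estimated correlation). Cd68 averaged 50.1 ± 23.4 against 448 ± 124. Foam cell genes fell in 14 of 18 cases (14 adjusted over the list alone; adjusted p = 0.0891 with an estimated correlation). Soat1 differed by -2.52 ± 0.26. Matrix proteases and inhibitors fell in 14 of 21 cases (15 adjusted over the list alone; adjusted p = 0.0891 with an estimated correlation). Urokinase (Plau) differed by -2.60 ± 0.22. Cytokine, chemokine and adhesion genes fell in 21 of 35 cases (26 adjusted over the list alone; adjusted p = 0.135 with an estimated correlation). Vcam1 averaged 98.1 ± 51.7 against 538 ± 41.3. Collagen and matrix genes fell in 17 of 21 cases (20 adjusted over the list alone; adjusted p = 0.263 with an estimated correlation). The small proteoglycan Lum differed by -2.72 ± 0.42. Modulated smooth muscle and cartilage genes fell in 12 of 16 cases (13 adjusted over the list alone; adjusted p = 0.135 with an estimated correlation). Markers of other tissues moved with these groups: skeletal muscle genes rose in 11 of 13 cases (13 adjusted over the list alone; adjusted p = 0.386 with an estimated correlation) and brown adipocyte genes in 4 of 12 (9 adjusted over the list alone; adjusted p = 0.386 with an estimated correlation), Acta1 being 131.8 to 608.4 in EKO/hA-I and 2.801 to 18.71 in EKO. Erythroid genes fell in 3 of 9 cases (6 adjusted over the list alone; adjusted p = 0.471 with an estimated correlation), with mean log2 levels of 5.68 against 7.01, a call of the list lost without EKO/hA-I replicate 2 or with brown fat and skeletal muscle terms. In total 2668 genes passed, 844 higher and 1824 lower (ranges apart for 40.6% of all genes, 10% by chance). The count was 1415 without EKO replicate 1, 1561 without EKO/hA-I replicate 1 and 1495, 1269 and 1402 with brown fat, with brown fat and skeletal muscle, and with all 4 tissue terms. Glb1, a member of both the lysosome and the sphingolipid list, lies among genes on chromosome 9 that differed between these genotypes on either diet. Without Glb1 the lysosome and sphingolipid lists had adjusted p = 0.0198 and 0.0215 with an estimated correlation.

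Many genes moved in opposite directions in these 2 comparisons. Of the genes higher in EKO than in WT, 1227 (58.6%) were lower in EKO/hA-I than in EKO, where unrelated lists would share 270. In 100 simulations without group effects on the same libraries 0 were shared. These called a median of 0 genes in either comparison, so they set no level for lists of this length. Their highest counts were 432 in EKO against WT and 6 in EKO/hA-I against EKO. Of those lower in EKO, 126 (12.4%) were higher in EKO/hA-I, and 4 genes moved the same way in both comparisons. The lysosome list had 40 of 43 risen genes fall again, the macrophage list 16 of 17, foam cell genes 13 of 14, sphingolipid genes 17 of 21 and matrix proteases 12 of 14. Cytokine genes did so in 20 of 31 cases, complement genes in 4 of 11, MHC class II genes in 0 of 7 and interferon-stimulated genes in 0 of 9. EKO/hA-I replicate 2 stood apart in mean log2 level of MHC class II (6.55 against 4.15 and 4.31, and 4.50 to 5.22 in EKO), B cell (5.46 against 1.34 and 1.68) and T cell genes (4.21 against 1.27 and 1.52). Without it 1 of 7 MHC class II genes fell, and the median of that list between EKO/hA-I and EKO was -0.71 in place of -0.12. Both comparisons use the same 3 EKO libraries, so part of the excess can come from these shared controls. Across genes the correlation of the log2 fold changes was -0.645, within what the simulations gave (mean -0.478, strongest -0.874), genes not being independent replicates. Their covariance was -0.324, against a simulated mean of -0.051 and a strongest of -0.151. The simulations held no group effect, and any shift of the shared EKO libraries makes the covariance more negative. The covariance therefore cannot tell how much of the opposite movement comes from these shared libraries.

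**Figure D3:**
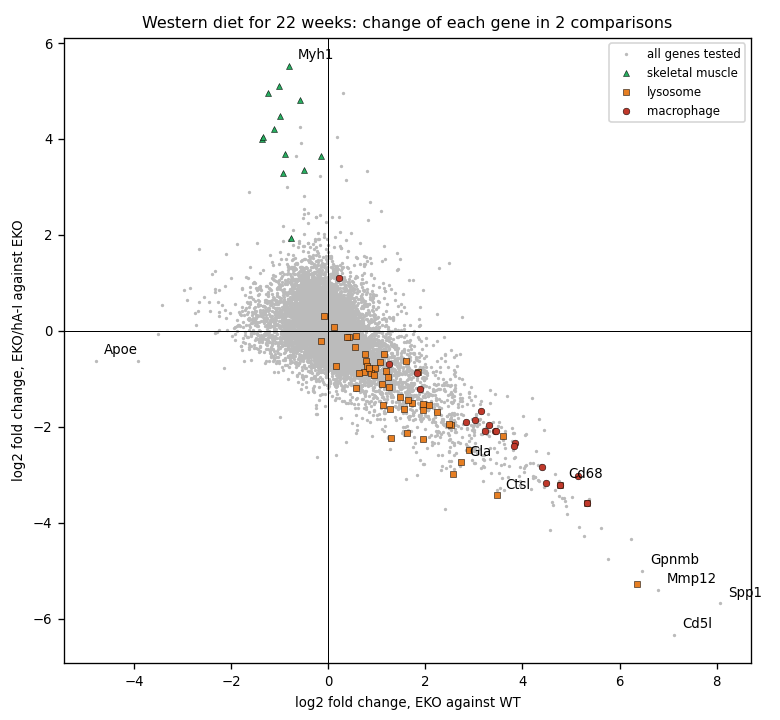
Log2 fold change of each of 14157 genes after 22 weeks of WD, EKO against WT (horizontal) and EKO/hA-I against EKO (vertical), with macrophage, lysosome and skeletal muscle genes marked. Macrophage and lysosome genes lie at the lower right, with Cd5l at 7.11 and -6.34, and skeletal muscle genes lie at the top, with Myh1 at -0.80 and 5.52.

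EKO/hA-I and WT aortas were also set against each other after 22 weeks of WD (n = 3 against 3), a comparison chosen after the data were examined. Macrophage markers were higher in EKO/hA-I than in WT in 15 of 18 cases (16 adjusted over the list alone; adjusted p = 0.485 with an estimated correlation). The complement subunit C1qa averaged 149.5 ± 67.5 against 56.3 ± 18.8 (1.36 ± 0.32, adjusted p = 0.0063, limma) and the signalling adaptor Tyrobp differed by 1.42 ± 0.36. MHC class II genes rose in 7 of 11 cases (7 adjusted over the list alone; adjusted p = 0.485 with an estimated correlation). H2-Ab1 differed by 1.85 ± 0.39. Their mean log2 level was 6.55 in EKO/hA-I replicate 2, 4.15 and 4.31 in the other 2 and 3.20 to 4.08 in WT, and without replicate 2 the list's median was 0.82 in place of 1.32. B cell genes moved with that library (5.46, against 1.34 and 1.68, and 1.34 to 2.01 in WT), and so did T cell genes (4.21, against 1.27 and 1.52), which spanned 0.95 to 5.09 in WT. Lysosome genes split, 9 higher and 4 lower of 49 (11 adjusted over the list alone; adjusted p = 0.662 with an estimated correlation). The sialidase Neu1 differed by 0.66 ± 0.11 and Glb1 by -0.94 ± 0.18. The list's call was lost without WT replicate 3 (adjusted p = 0.12), without EKO/hA-I replicate 3 (0.572) and in a fit of these 6 libraries. Contractile smooth muscle genes were lower in 12 of 16 cases (14 adjusted over the list alone; adjusted p = 0.485 with an estimated correlation). Itga8 averaged 492 ± 273 against 2004 ± 406. Skeletal muscle markers moved with the group, with a median of 3.08 (adjusted p = 0.546 with an estimated correlation). Brown adipocyte genes did so too, with a mean log2 level of 8.16 in EKO/hA-I against 7.27 in WT and ranges apart. Erythroid genes had 5.68 against 7.18, with ranges that overlapped. Apoe differed by -5.41 ± 0.31. Of 2544 genes that passed, 1205 were higher and 1339 lower (ranges apart for 44.4% of all genes, 10% by chance). The count was 887 without EKO/hA-I replicate 2, 996 and 1205 without WT replicates 2 and 3, and 928, 464 and 287 with brown fat, with brown fat and skeletal muscle, and with all 4 tissue terms. Those terms ended the calls of C1qa, Tyrobp, Itga8, H2-Ab1 and, with all 4, the contractile smooth muscle list, and a fit of these 6 libraries that of C1qa.

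On chow for 22 weeks, EKO/hA-I aortas again held less of the macrophage transcripts than EKO aortas (n = 3 against 3). Y-linked transcripts were missing from 0 of the 3 EKO/hA-I and 2 of the 3 EKO libraries, so sex was not balanced here. Spp1 averaged 2.36 ± 0.8 against 401 ± 153 (-6.86 ± 1.24, adjusted p = 0.00064, limma), Cd5l 12.6 ± 14.6 against 314 ± 60.6 (-5.32 ± 1.05, adjusted p = 0.0011) and the elastase Mmp12 differed by -4.52 ± 0.81 (adjusted p = 0.00064). The ectonucleotidase Nt5e averaged 47.9 ± 8.26 against 7.41 ± 1.25 (2.53 ± 0.31). Macrophage markers fell in 11 of 18 cases (11 adjusted over the list alone; adjusted p = 0.709 with an estimated correlation). Cd68 averaged 13 ± 2.43 against 65.7 ± 18.5. Foam cell genes fell in 14 of 18 and rose in 1 (15 adjusted over the list alone; adjusted p = 0.637 with an estimated correlation). Lgals3 averaged 15.1 ± 2.76 against 117 ± 13.9. Lysosome genes fell in 18 of 49 cases and rose in 2 (22 adjusted over the list alone; adjusted p = 0.709 with an estimated correlation). The protease Ctsd differed by -1.22 ± 0.20. Mitochondrial respiration genes fell in 27 of 27 cases (27 adjusted over the list alone; adjusted p = 0.679 with an estimated correlation), white adipocyte genes in 12 of 15 (14 adjusted over the list alone; adjusted p = 0.679 with an estimated correlation) and brown adipocyte genes in 8 of 12 (8 adjusted over the list alone; adjusted p = 0.709 with an estimated correlation), Ucp1 being 852.6 to 1084 in EKO/hA-I and 2334 to 4491 in EKO. Erythroid genes fell in 7 of 9 cases (9 adjusted over the list alone; adjusted p = 0.679 with an estimated correlation) and mast cell genes in 4 of 7 (4 adjusted over the list alone; adjusted p = 0.679 with an estimated correlation), with mean log2 levels of 5.59 against 7.45 and 2.48 against 3.72. Collagen and matrix genes rose in 14 of 21 cases (17 adjusted over the list alone; adjusted p = 0.709 with an estimated correlation). Col3a1 differed by 1.73 ± 0.38, a call that ended with tissue terms. Adjusted p passed for 4046 genes, 1937 higher and 2109 lower (ranges apart for 45% of all genes, 10% by chance). The count was 2125 without EKO/hA-I replicate 3, 2342 without EKO replicate 3 and 1165, 643 and 423 with brown fat, with brown fat and skeletal muscle, and with all 4 tissue terms.

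At 6 weeks few genes separated EKO/hA-I from EKO. On chow (n = 2 against 3) 11 genes passed limma, 5 higher and 6 lower (ranges apart for 35.8% of all genes, 20% by chance), and 1860 had an unadjusted p under 0.05. The neurexophilin-family gene Nxpe4 averaged 1.81 ± 0.176 against 8.72 ± 0.649 (-1.79 ± 0.32, adjusted p = 0.012). Its adjusted p was 0.052 and 0.051 without EKO replicates 2 and 3, 0.12 and 0.27 without EKO/hA-I replicates 1 and 2 and 0.087 with a pseudocount of 5. No gene of the B cell list passed over all genes, although 11 of 12 passed when adjusted over the list alone (adjusted p = 0.467 with an estimated correlation), with a median of 2.15. Ranges were apart for other lists too, also with 0 genes past the test over all genes. Mean log2 levels were 4.64 against 3.40 for MHC class II (adjusted p = 0.467 with an estimated correlation), 4.16 against 2.97 for plasma cell (adjusted p = 0.467 with an estimated correlation) and 3.57 against 2.61 for mast cell genes (adjusted p = 0.467 with an estimated correlation). They were 5.04 against 6.30 for erythroid (adjusted p = 0.467 with an estimated correlation) and 7.38 against 8.40 for heat shock genes (adjusted p = 0.467 with an estimated correlation). Fat and muscle lists had ranges apart as well. Brown adipocyte genes lay at 7.18 against 6.53, white adipocyte genes at 9.39 against 8.80 and mitochondrial respiration genes at 8.41 against 7.85. Contractile smooth muscle genes were lower, at 9.10 against 9.93. The plasma cell call was lost without EKO replicate 1 or with a pseudocount of 5. The count was 157 and 5 without EKO replicates 1 and 3, 4 without EKO/hA-I replicate 2, 3 without the 2 libraries of highest nerve genes and 0 in a fit of these 5 libraries, and both of the last settings ended the call of Nxpe4.
On WD (n = 3 against 3) 10 genes passed, 4 higher and 6 lower (ranges apart for 10.5% of all genes, 10% by chance), and 748 had an unadjusted p under 0.05. Nxpe4 averaged 2.39 ± 0.283 against 10.4 ± 3.09 (-1.71 ± 0.28, adjusted p = 0.0054) and Morf4l1b 135 ± 10.5 against 27.1 ± 3.32 (2.28 ± 0.25), a gene that shares reads with a near-identical copy, so its level is uncertain. The adjusted p of Nxpe4 was 0.053 without EKO replicate 1 or EKO/hA-I replicate 1. Of the 49 lysosome genes, 1 fell (1 adjusted over the list alone; adjusted p = 0.668 with an estimated correlation), a call lost without EKO replicate 1. Skeletal muscle genes had a median of 2.17 with 0 past the test (adjusted p = 0.668 with an estimated correlation), Acta1 reaching 766.7 in EKO/hA-I replicate 2, without which the list had adjusted p = 0.472. The count was 6 without EKO replicate 3, 6 and 17 without EKO/hA-I replicates 1 and 3, 4 in a fit of these 6 libraries, Nxpe4 not among them, and 20 with a brown fat term.
Whether the genotype difference on WD depended on the duration was tested directly. The interaction held for 725 genes, 638 of them with a lower EKO/hA-I level relative to EKO at 22 than at 6 weeks. Lysosome genes were lower in 32 of 49 cases (38 adjusted over the list alone; adjusted p = 0.0336 with an estimated correlation). Ctsl differed by -3.24 ± 0.34 (adjusted p = 9.8e-06) and Gla by -2.42 ± 0.27. Sphingolipid genes were lower in 13 of 47 cases (15 adjusted over the list alone; adjusted p = 0.0336 with an estimated correlation). Macrophage markers were lower in 13 of 18 cases (17 adjusted over the list alone; adjusted p = 0.161 with an estimated correlation). Msr1 differed by -2.97 ± 0.57. The count was 1107, 398 and 457 without EKO WD 6 weeks replicates 1, 2 and 3, 441 and 471 without EKO WD 22 weeks replicates 1 and 3, 442 without EKO/hA-I WD 22 weeks replicate 1, 406 in a fit of these 12 libraries and 402 with a brown fat term.

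**Figure D4:**
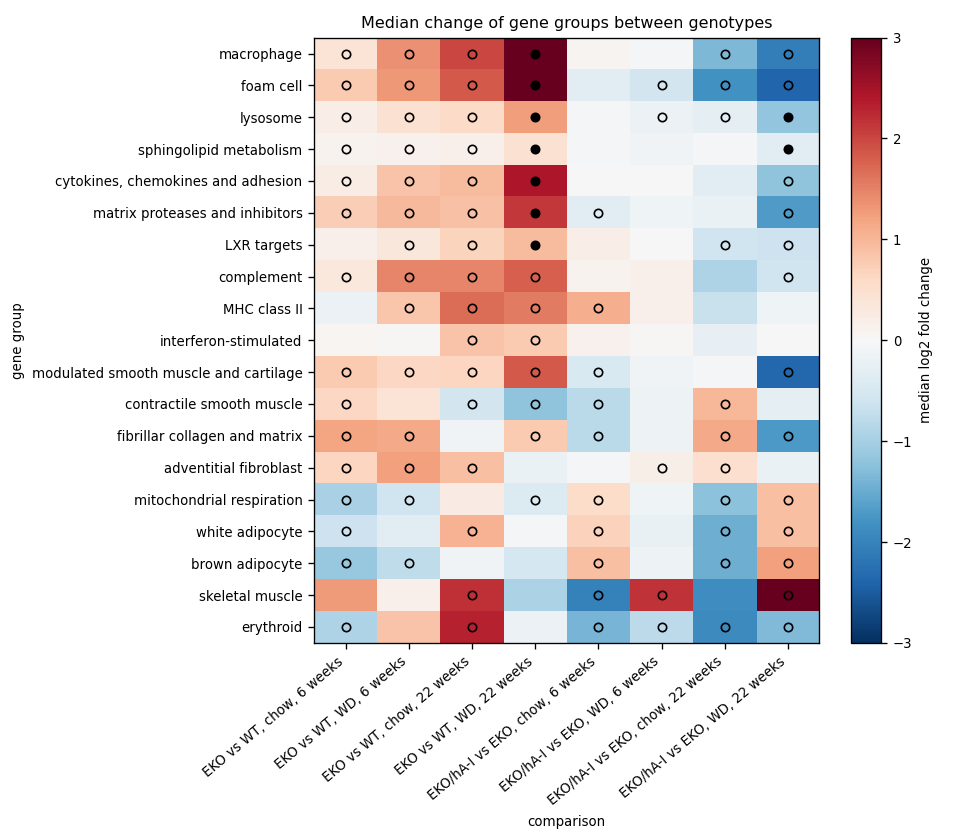
Median log2 fold change (colour, limited to 3 in size) of 19 gene lists in the 8 comparisons between genotypes, with an open circle where the list was called with a preset correlation and a filled one where it was also called with an estimated correlation. Filled circles appear for 7 lists in EKO against WT and 2 lists in EKO/hA-I against EKO, both after 22 weeks of WD.

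The effect of diet within EKO mice was compared at 22 weeks (n = 3 against 3). WD raised Spp1 to 9604 ± 2323 against 401 ± 153 on chow (4.61 ± 1.24, adjusted p = 0.0098, limma), Mmp13 to 56.1 ± 14.1 against 2.43 ± 0.779 (4.05 ± 0.46, adjusted p = 7.8e-07), Col2a1 to 36.1 ± 16.6 against 2.42 ± 3.53 and the joint lubricant Prg4 to 470.3 ± 319 against 36.3 ± 15.3. Rises of 3.82 ± 0.41 for Cemip, 3.52 ± 0.56 for Itgax, 3.47 ± 0.44 for the leukocyte receptor Lilr4b and 3.45 ± 0.88 for the acute-phase gene Saa3 followed. The transcription factor Cebpb fell to 27.9 ± 5.72 against 96.2 ± 8.29 (-1.77 ± 0.42, adjusted p = 0.0038). Lysosome genes rose in 41 of 49 cases (43 adjusted over the list alone; adjusted p = 0.0237 with an estimated correlation). Ctsl averaged 3818 ± 1346 against 580.3 ± 22.8 and Gla differed by 2.37 ± 0.19. Sphingolipid genes rose in 21 of 47 and fell in 1 (23 adjusted over the list alone; adjusted p = 0.0136 with an estimated correlation). Asah1 differed by 1.23 ± 0.14. Macrophage markers rose in 17 of 18 cases (17 adjusted over the list alone; adjusted p = 0.177 with an estimated correlation). Msr1 differed by 3.14 ± 0.40. Foam cell genes rose in 13 of 18 cases (14 adjusted over the list alone; adjusted p = 0.139 with an estimated correlation). Cytokine, chemokine and adhesion genes rose in 28 of 35 cases (31 adjusted over the list alone; adjusted p = 0.0878 with an estimated correlation). Cxcl16 differed by 2.70 ± 0.30. Collagen and matrix genes rose in 14 of 21 cases (15 adjusted over the list alone; adjusted p = 0.424 with an estimated correlation). Thbs1 differed by 3.33 ± 0.51. Mitochondrial respiration genes fell in 12 of 27 cases (20 adjusted over the list alone; adjusted p = 0.424 with an estimated correlation), and brown adipocyte genes had a median of -0.94 between these groups (adjusted p = 0.462 with an estimated correlation). In total 2644 genes passed, 1964 higher and 680 lower on WD (ranges apart for 37% of all genes, 10% by chance), and the count was 1411 without EKO WD replicate 1 and 1670 in a fit of these 6 libraries.
Tested as an interaction, the diet effect differed between EKO and WT for 879 genes, 707 of them more positive in EKO. Gla differed by 2.24 ± 0.27 (adjusted p = 4.2e-05), Ctsl by 2.18 ± 0.34, Mmp13 by 3.78 ± 0.65 and Msr1 by 2.82 ± 0.57, while Lep differed by -4.95 ± 0.89 (adjusted p = 0.001). Lysosome genes were more positive in 24 of 49 cases (37 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation). The count was 508 without EKO WD 22 weeks replicate 1 and 361 in a fit of these 12 libraries. It was 1686, 1303 and 682 with brown fat, with brown fat and skeletal muscle, and with all 4 tissue terms.

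In EKO/hA-I aortas at 22 weeks the diets differed in more genes than in any other comparison made, 5409 of 14157, with 2928 higher and 2481 lower on WD (n = 3 against 3; ranges apart for 51.6% of all genes, 10% by chance). Skeletal muscle genes rose in 13 of 13 cases (13 adjusted over the list alone; adjusted p = 0.519 with an estimated correlation). Myh1 averaged 264 ± 193 against 0.679 ± 0.462 (6.91 ± 1.58, adjusted p = 0.0023, limma) and the calcium pump Atp2a1 411 ± 281 against 3.72 ± 3.08 (6.44 ± 1.60). Mitochondrial respiration genes rose in 27 of 27 cases (27 adjusted over the list alone; adjusted p = 0.519 with an estimated correlation), and brown adipocyte genes rose in 9 of 12 and fell in 1 (9 adjusted over the list alone; adjusted p = 0.519 with an estimated correlation), Ucp1 being 3245 to 4366 on WD and 852.6 to 1084 on chow. Collagen and matrix genes fell in 19 of 21 cases (19 adjusted over the list alone; adjusted p = 0.519 with an estimated correlation). Postn averaged 255 ± 85.2 against 1182 ± 192 (-2.25 ± 0.32, adjusted p = 0.00019). Contractile smooth muscle genes fell in 14 of 16 cases and rose in 1 (14 adjusted over the list alone; adjusted p = 0.519 with an estimated correlation). Smooth muscle actin (Acta2) averaged 2147 ± 847 against 11429 ± 3277. The Wnt inhibitors Wif1 and Sost averaged 1.64 ± 1.62 against 24.8 ± 6.21 and 113 ± 76.2 against 835 ± 329. Macrophage markers rose in 12 of 18 cases (13 adjusted over the list alone; adjusted p = 0.519 with an estimated correlation), and lysosome genes rose in 15 and fell in 8 of 49 cases without a list call (adjusted p = 0.855 with an estimated correlation). With a brown fat term 2 genes passed, with brown fat and skeletal muscle 1, and with all 4 tissue terms 2, and these terms ended the calls of Wif1, Sost, Acta2 and Postn and of the mitochondrial, contractile smooth muscle and collagen lists.
The diet effect differed between EKO/hA-I and EKO for 4840 genes, 2210 more positive and 2630 more negative in EKO/hA-I. Genes of collagen and matrix were more negative in 20 of 21 cases (20 adjusted over the list alone; adjusted p = 0.376 with an estimated correlation) and lysosome genes in 30 of 49, with 2 more positive (30 adjusted over the list alone; adjusted p = 0.376 with an estimated correlation). Asah1 differed by -1.76 ± 0.20 (adjusted p = 7.2e-06). Mitochondrial respiration genes were more positive in 27 of 27 cases (27 adjusted over the list alone; adjusted p = 0.376 with an estimated correlation). The count was 120 with a brown fat term, 0 with brown fat and skeletal muscle, which ended the call of Asah1 (6263 genes having an unadjusted p under 0.05 without terms), and 16 with all 4.

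The other diet comparisons called fewer genes. In WT at 22 weeks (n = 3 against 3), 193 genes passed limma (131 higher, 62 lower; ranges apart for 16.9% of all genes, 10% by chance). The endothelial lipase Lipg averaged 0.905 ± 0.138 against 8.54 ± 4.97 (-2.21 ± 0.37, adjusted p = 0.0067) and Lep 69.8 ± 14.8 against 7.62 ± 5.12 (3.17 ± 0.63), with an adjusted p for Lep of 0.056 without chow replicate 3 and 0.064 and 0.068 without WD replicates 1 and 2. Adventitial fibroblast genes rose in 2 of 12 cases (11 adjusted over the list alone; adjusted p = 0.471 with an estimated correlation). Library ranges were apart for other lists as well. Mean log2 levels on WD against chow were 7.18 against 5.62 for erythroid, 3.66 against 2.71 for mast cell and 3.70 against 1.55 for skeletal muscle genes. Cardiac muscle genes went the other way, at 2.37 against 5.07. The count was 47 without chow replicate 3, 19, 15 and 349 without WD replicates 1, 2 and 3, 555 with brown fat and 8 with all 4 tissue terms, which ended both calls, and 0 in a fit of these 6 libraries (2295 at an unadjusted p under 0.05 in the full fit).
In WT at 6 weeks (n = 3 against 3), 203 genes passed (118 higher, 85 lower; ranges apart for 23.5% of all genes, 10% by chance). The vessel-stabilising ligand Angpt1 averaged 4.44 ± 1.23 against 16.4 ± 4.63 (-1.67 ± 0.26, adjusted p = 0.0045). Heat shock genes, a sign of handling, rose in 4 of 12 cases (7 adjusted over the list alone; adjusted p = 0.346 with an estimated correlation). Erythroid genes passed in 0 of 9 cases (8 adjusted over the list alone; adjusted p = 0.416 with an estimated correlation), with mean log2 levels of 5.60 against 7.10, and the 1 measured long nuclear RNA spanned 3.41 to 3.63 against 4.47 to 5.66. The count was 10 and 24 without chow replicates 2 and 3, 21, 119 and 16 without WD replicates 1, 2 and 3, 3 in a fit of these 6 libraries, Angpt1 not among them, and 379 with a brown fat term, brown adipocyte genes having a median of 0.72 (adjusted p = 0.538 with an estimated correlation).
In EKO at 6 weeks (n = 3 against 3) 12 genes passed, 9 higher and 3 lower (ranges apart for 22.9% of all genes, 10% by chance), and 2849 had an unadjusted p under 0.05. No foam cell gene passed over all genes, but 11 of 18 did adjusted over the list alone (adjusted p = 0.327 with an estimated correlation), with a median of 1.30. The count was 20, 0 and 0 without chow replicates 1, 2 and 3, 45, 0 and 0 without WD replicates 1, 2 and 3, 2 without the 2 libraries of highest nerve genes (chow replicate 1 and another in EKO/hA-I), 0 in a fit of these 6 libraries, and 1, 1 and 0 with the tissue terms.
In EKO/hA-I at 6 weeks (n = 3 against 2) 1 gene passed, a lower one (ranges apart for 17.6% of all genes, 20% by chance), and 479 had an unadjusted p under 0.05. The count was 3 without chow replicate 1 and 0 without any 1 of the 3 WD replicates, in a fit of these 5 libraries, with a brown fat term, with a pseudocount of 0.1 or with a replicate block.

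Durations were compared within each genotype and diet, 22 against 6 weeks, a difference that includes 16 weeks of age. In EKO on WD (n = 3 against 3), Spp1 averaged 9604 ± 2323 against 316 ± 323 (5.37 ± 1.24, adjusted p = 0.0032, limma), Cemip 68.2 ± 23.7 against 1.45 ± 0.0809 (4.75 ± 0.41) and Col2a1 36.1 ± 16.6 against 0.435 ± 0.18 (4.57 ± 0.70), while the kallikrein Klk10 averaged 3.63 ± 2.18 against 19.5 ± 6.12 (-2.20 ± 0.43). Lysosome genes rose in 40 of 49 cases (44 adjusted over the list alone; adjusted p = 0.0152 with an estimated correlation). Ctsl differed by 2.98 ± 0.24. Sphingolipid genes rose in 17 of 47 cases (21 adjusted over the list alone; adjusted p = 0.0152 with an estimated correlation), macrophage markers in 17 of 18 (17 adjusted over the list alone; adjusted p = 0.0988 with an estimated correlation) and cytokine, chemokine and adhesion genes in 29 of 35 (32 adjusted over the list alone; adjusted p = 0.0598 with an estimated correlation). Circadian clock genes fell in 6 of 18 cases (10 adjusted over the list alone; adjusted p = 0.115 with an estimated correlation). The repressor Nr1d1 differed by -1.86 ± 0.33. Contractile smooth muscle genes fell in 6 of 16 cases (12 adjusted over the list alone; adjusted p = 0.456 with an estimated correlation). In total 1903 genes passed, 1482 higher and 421 lower (ranges apart for 29.7% of all genes, 10% by chance), and the count was 1221 without WD 6 weeks replicate 3 and 3184 with a brown fat term.
In EKO on chow (n = 3 against 3), 3829 genes passed (1885 higher, 1944 lower; ranges apart for 43.8% of all genes, 10% by chance). Cd5l averaged 314 ± 60.6 against 12.2 ± 0.939 (4.56 ± 1.05, adjusted p = 0.0035). Mitochondrial respiration genes rose in 25 of 27 cases (27 adjusted over the list alone; adjusted p = 0.677 with an estimated correlation). Genes of collagen and matrix fell in 13 of 21 cases (15 adjusted over the list alone; adjusted p = 0.677 with an estimated correlation). Postn differed by -1.78 ± 0.32. Macrophage markers rose in 10 of 18 (12 adjusted over the list alone; adjusted p = 0.677 with an estimated correlation). Erythroid genes rose in 2 of 9 cases (4 adjusted over the list alone; adjusted p = 0.677 with an estimated correlation), mast cell genes in 3 of 7 (5 adjusted over the list alone; adjusted p = 0.677 with an estimated correlation) and MHC class II genes in 5 of 11 (5 adjusted over the list alone; adjusted p = 0.677 with an estimated correlation). Their mean log2 levels were 7.45 against 6.30, 3.72 against 2.61 and 4.53 against 3.40, and the erythroid call was lost without chow 6 weeks replicate 1 or chow 22 weeks replicate 2. Ucp1 was 698.2 to 1024 at 6 weeks and 2334 to 4491 at 22 weeks. The count was 1455 without chow 6 weeks replicate 3, 2344 and 2279 without chow 22 weeks replicates 1 and 3, 2436 in a fit of these 6 libraries and 1373 with a brown fat term, which also ended the call of the collagen list.
In WT on WD (n = 3 against 3), 945 genes passed (455 higher, 490 lower; ranges apart for 33.3% of all genes, 10% by chance). Lep averaged 69.8 ± 14.8 against 7.94 ± 5.59 (3.22 ± 0.63, adjusted p = 0.0048). Adventitial fibroblast genes rose in 8 of 12 cases (11 adjusted over the list alone; adjusted p = 0.504 with an estimated correlation). Pdgfra differed by 1.54 ± 0.26. Endothelial genes fell in 5 of 12 (7 adjusted over the list alone; adjusted p = 0.504 with an estimated correlation). Endoglin (Eng) differed by -1.11 ± 0.21. Heat shock genes, a sign of handling, fell in 5 of 12 cases (9 adjusted over the list alone; adjusted p = 0.504 with an estimated correlation), from a mean log2 level of 8.25 to 7.25. Erythroid genes rose in 5 of 9 cases (8 adjusted over the list alone; adjusted p = 0.504 with an estimated correlation), from 5.60 to 7.18. Brown adipocyte genes had a median of -0.83 (adjusted p = 0.581 with an estimated correlation). The count was 228 and 550 without WD 6 weeks replicates 1 and 3, 278 and 150 without WD 22 weeks replicates 1 and 2, 177 in a fit of these 6 libraries and 30, 1 and 2 with the tissue terms, which ended the calls of Lep, Pdgfra and Eng.
Few genes differed by duration elsewhere. In WT on chow (n = 3 against 3) 17 genes passed, 5 higher and 12 lower (ranges apart for 11.6% of all genes, 10% by chance), and 1536 had an unadjusted p under 0.05. The eosinophil chemokine Ccl11 averaged 9.27 ± 2.47 against 29.7 ± 4.61 (-1.59 ± 0.25, adjusted p = 0.0068, and 0.052 without chow 22 weeks replicate 3). The count was 10 and 5 without chow 6 weeks replicates 1 and 2, 91 and 3 without chow 22 weeks replicates 2 and 3, 0 in a fit of these 6 libraries, 36 after rescaling, 39 with a sex term, 32 with a replicate block and 811, 785 and 139 with the tissue terms.
In EKO/hA-I on chow (n = 3 against 2) 1 gene passed, the oxidoreductase-like Gfod2 (-0.76 ± 0.13; ranges apart for 37.6% of all genes, 20% by chance). Its adjusted p was 0.069 and 0.33 without chow 6 weeks replicates 1 and 2 and 0.19 and 0.11 without chow 22 weeks replicates 2 and 3, and 1731 had an unadjusted p under 0.05. The count was 14 without chow 6 weeks replicate 1 and 0 without chow 22 weeks replicate 2 or 3, in a fit of these 5 libraries, after rescaling, with a sex term, with a replicate block or with tissue terms, and 4 with a pseudocount of 5.
In EKO/hA-I on WD (n = 3 against 3) 10 genes passed, 6 higher and 4 lower (ranges apart for 29.4% of all genes, 10% by chance), and 2863 had an unadjusted p under 0.05. The basement membrane chain Col4a3 averaged 6.37 ± 0.652 against 26 ± 10.8 (-1.80 ± 0.31, adjusted p = 0.013, 0.2 without WD 6 weeks replicate 3 and 0.12 without WD 22 weeks replicate 2). The count was 22 and 3 without WD 6 weeks replicates 2 and 3, 18, 3 and 49 without WD 22 weeks replicates 1, 2 and 3, 0 in a fit of these 6 libraries, 17 with a pseudocount of 5, 16 with a replicate block and 3, 2 and 2 with the tissue terms, which ended the call of Col4a3.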

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

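The tests of sex in the diet comparison, of the sides of other groupings, of the smooth muscle share and of the chromosomes were chosen after the result was seen, and the tissue terms were added after the data were examined.

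A test of the difference between groups brought up 3 results. The diet effect at 22 weeks differed between EKO and WT for 879 genes and between EKO/hA-I and EKO for 4840 genes, and the difference between EKO/hA-I and EKO on WD differed between 22 and 6 weeks for 725 genes. Among 100 groupings of the same 12 libraries, the real one and 99 drawn at random, 6 with the real one gave at least the 879 (highest other 2976) and 6 at least the 725 (highest other 2248), so chance cannot be excluded for these counts. For the 4840, the real grouping alone (1 of 100) gave as many, with a highest other of 3937. Drawn groupings mix libraries that differ by genotype, diet or duration, so they set no level for an interaction alone. This rank therefore does not exclude chance. The grouping that gave 3937 sets the same 2 sides against each other as the real one, and the highest with other sides gave 3571. Groupings that call over 3 times the real count point to a structure of the samples. Counted after the result was seen, all 5 other groupings that reached the 879, and all 5 that reached the 725, kept the 3 EKO libraries on WD for 22 weeks on one side of the difference, as did 5 and 16 of the 94 that gave fewer, so this structure includes a group compared.

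The largest count, 5409 genes between diets in EKO/hA-I at 22 weeks, was weighed. Sex is argued against, since a sex term left 5289 genes. Different amounts of brown fat and skeletal muscle in the aortas may account for much of it: differences predicted from the slopes of these 2 marker lists in 29 other libraries correlated with the observed ones at r = 0.75 across 14132 genes (highest of 100 shuffles 0.64), genes not being independent replicates, and 93.5% of 5386 called genes had the predicted sign. A brown fat term ended the calls through their size and not their error, the median size going from 0.86 to 0.31 and the median SE from 0.237 to 0.223, Ucp1 lay at 3245 to 4366 on WD against 852.6 to 1084 on chow and Acta1 at 131.8 to 608.4 on WD against 1.404 to 6.099 on chow although fat around the vessel had been removed. An effect of diet on the tissue around the vessel, or on the wall itself, stays open and was not tested.

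Macrophage and lysosome genes higher in EKO than in WT on WD at 22 weeks were weighed too. Brown fat and skeletal muscle are argued against, since all 58 members that rose still rose with both terms, and so is a lower share of smooth muscle cells raising all other cell types, since the 90th percentile of endothelial and adventitial fibroblast members was 0.83 and the macrophage median 3.37. More macrophages, each with the lysosome level of other libraries, cannot be told apart from more lysosomal expression per macrophage. A line through the other 32 libraries predicted the lysosome level, and the observed level was 1.57 times that (1.32 to 1.69 in the 3 libraries), but their macrophage levels of 16.7 to 24.5 lie beyond the 5.3 that the line reaches. Growth of lesions rich in macrophages in EKO mice on WD stays among the open explanations and was not tested.

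Genes differing one way between genotypes in at least 3 of the 4 pairs of diet and time were weighed last. Between EKO/hA-I and EKO there were 8, and all 8 passed with a sex term, which argues against sex. Of these 8, 5 lie on chromosome 9 by their symbols in GRCm38 (Glb1, Srprb and Nxpe4 among them, named here after their values were seen). All 5 were lower in EKO/hA-I. This share was 62.5% against 5.7% of tested genes (one-sided Fisher's exact test, p = 0.00067 after multiplying by 23 chromosome labels of the annotation). Asking for all 4 pairs gave 4 of 7 (Fisher's exact p = 0.0074), so a candidate explanation is a stretch of chromosome 9 that differs between the lines apart from the transgene. For EKO against WT, 34 of 331 such genes lie on chromosome 7 with Apoe, 10.3% against 7.7% (Fisher's exact p = 0.053, and 0.04 for 5 of 25 genes in all 4 pairs). Those 5, named after their values were seen, are Apoc1, Sae1, Lgals4, Cep89 and Vmn2r29. The test takes the chromosome as a whole, so it cannot decide on variants around Apoe, which stay open.

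For the comparisons of 3 with 3 libraries, 10 splits exist, too few for a share under 0.05. In EKO against WT the real split gave 704, 770, 2165 and 3114 genes (chow and WD at 6 weeks, chow and WD at 22 weeks), and the highest other split 94, 1, 4 and 0. In EKO/hA-I against EKO these values were 10 and 0 (WD, 6 weeks), 4046 and 0 (chow, 22 weeks) and 2668 and 7 (WD, 22 weeks), and in EKO/hA-I against WT 2544 and 105. Between diets they were 203 and 0 in WT and 12 and 0 in EKO at 6 weeks, and 193 and 0 in WT, 2644 and 0 in EKO and 5409 and 1 in EKO/hA-I at 22 weeks. Between durations they were 3829 and 2 in EKO on chow, 945 and 1 in WT on WD and 1903 and 1 in EKO on WD. In the last 2, residuals of same-numbered libraries correlated above 0.1 in every pair, though no label states a pairing. There the 3 other splits that part as many such pairs gave at most 1 gene. Each of these splits exchanges the 2 libraries of 1 pair. In WT on chow between durations 2 of the 10 splits, the real one among them, gave at least its 17 genes, and the highest, 566, set WT chow 6 weeks replicates 1 and 2 and 22 weeks replicate 2 against the rest, which points to a structure of the samples. In EKO/hA-I on WD between durations 2 of the 10, again with the real one, gave at least its 10 genes, with a highest of 18.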

How the results depend on the processing

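The tissue terms, the sex term, median-ratio rescaling and the omission of libraries with high nerve genes were chosen after seeing the data, and the other settings were planned. DESeq2 and RLE size factors were planned but not run, since the table holds no counts, and other thresholds had been planned only for a table of the authors' own test results. Dropping the filter changed no comparison count by over 1.5 times and ended no call of a gene or list named in the text, and with no setting did such a call turn round. For the changes given next the cause was not tested, except where fewer libraries entered a fit.

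Fitted with only the groups compared, fewer genes passed in EKO against WT on chow at 6 weeks (9 in place of 704), on WD at 6 weeks (1, of 770) and on chow at 22 weeks (11, of 2165), and in EKO/hA-I against EKO at 6 weeks on chow (0, of 11) and WD (4, of 10). Between diets, 3 of 203 passed in WT at 6 weeks, 0 of 12 in EKO at 6 weeks, 0 of 1 in EKO/hA-I at 6 weeks, 0 of 193 in WT at 22 weeks and 1670 of 2644 in EKO at 22 weeks. Between durations the counts were 0 (WT chow), 2436 (EKO chow), 0 (EKO/hA-I chow), 177 (WT WD) and 0 (EKO/hA-I WD), and for the interactions 361 (diet, EKO against WT) and 406 (genotype and duration). Such a fit estimates the spread from 5 to 12 libraries in place of 35. It ended the calls of 23 of 141 gene results and 1 of 107 list results. Here and below these are only results described in the text, so such shares are no measure of stability.

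With a brown fat term, then with brown fat and skeletal muscle, then with all 4 tissue terms, EKO against WT gave 122, 115 and 111 genes on chow and 277, 267 and 372 on WD at 6 weeks. On chow at 22 weeks the counts were 3527, 2857 and 1935. EKO/hA-I against EKO gave 20, 17 and 12 on WD at 6 weeks. At 22 weeks it gave 1165, 643 and 423 on chow and 1495, 1269 and 1402 on WD. EKO/hA-I against WT gave 928, 464 and 287. Diets at 6 weeks gave 379, 370 and 247 in WT, 1, 1 and 0 in EKO and, with brown fat, 0 in EKO/hA-I. Diets at 22 weeks gave 555, 271 and 8 in WT and 2, 1 and 2 in EKO/hA-I. Durations gave 811, 785 and 139 (WT chow), 1373, 1230 and 1178 (EKO chow), 0, 0 and 0 (EKO/hA-I chow), 30, 1 and 2 (WT WD), 3184, 3024 and 2980 (EKO WD) and 3, 2 and 2 (EKO/hA-I WD). The interactions gave 1686, 1303 and 682 (diet, EKO against WT), 120, 0 and 16 (diet, EKO/hA-I against EKO) and 402, 386 and 533 (genotype and duration). Of 138 gene results tested with these terms, 10, 16 and 18 lost their call, and of 94 list results 2, 4 and 6.

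With a pseudocount of 0.1 the diet count of EKO/hA-I at 6 weeks went from 1 to 0, and with a pseudocount of 5 the duration counts of EKO/hA-I became 4 on chow and 17 on WD. A replicate block gave 32 for WT on chow, 16 for EKO/hA-I on WD and 0 for EKO/hA-I on chow between durations, and 0 for EKO/hA-I between diets at 6 weeks. In 2 comparisons of durations all 3 pairs of same-numbered libraries had residuals correlated above 0.1. There the blocked counts were 993 (WT WD) and 2035 (EKO WD) in place of 945 and 1903, and the block changed no call named there. A sex term gave 39 for WT on chow between durations and 0 for EKO/hA-I on chow, and rescaling 36 and 0. Without the 2 libraries of highest nerve genes the counts were 1094 (EKO against WT) and 3 (EKO/hA-I against EKO) on chow at 6 weeks and 2 (diets in EKO at 6 weeks). An estimated correlation ended 92 of 107 list calls, and fry did not call 16 of them. Rescaling, a sex term, the block and a pseudocount of 5 each ended 1 of 141 gene calls, and the omission of the nerve libraries 2 of 8. A pseudocount of 5 also ended 1 of 107 list calls and that omission 2 of 16.

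With each library left out in turn, counts ranged in EKO against WT from 16 to 1533 (chow, 6 weeks), 63 to 1127 (WD, 6 weeks), 745 to 2492 (chow, 22 weeks) and 2294 to 2868 (WD, 22 weeks). In EKO/hA-I against EKO they ranged from 4 to 157 and 6 to 17 (chow and WD, 6 weeks), 2125 to 3914 and 1415 to 2969 (chow and WD, 22 weeks), and in EKO/hA-I against WT from 887 to 2228. Between diets they ranged from 10 to 170 (WT), 0 to 45 (EKO) and 0 to 3 (EKO/hA-I) at 6 weeks and from 15 to 349, 1411 to 2772 and 3608 to 5007 at 22 weeks. Between durations they ranged from 3 to 91, 1455 to 3805 and 0 to 14 on chow and from 150 to 1028, 1221 to 1756 and 3 to 49 on WD, in the same order. Leaving out 1 library ended 9 of 141 gene calls and 7 of 107 list calls, but most genes of the naming rule that lost their call this way are not described and so not among the 141, so the share of genes is no measure of stability. The interactions ranged from 508 to 1039 (diet, EKO against WT), 3492 to 5029 (diet, EKO/hA-I against EKO) and 398 to 1107 (genotype and duration). Where 1 library of EKO/hA-I on chow at 6 weeks was left out, the lone one was assumed to vary like the other groups. WT WD 22 weeks replicate 3, whose labels disagree, left 2294 genes in EKO against WT when omitted. Depth limits genes near 0, where 1 read in the library of fewest reads, 6850000, is a large step on the log scale.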

Other observations

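The lists were fixed before the data were examined, and which of them to describe here was chosen after their results were seen. In EKO/hA-I against EKO on WD at 22 weeks (n = 3 against 3) LXR targets fell in 7 of 13 cases (7 adjusted over the list alone; adjusted p = 0.386 with an estimated correlation), with the phospholipid transfer protein Pltp at -1.74 ± 0.24 (adjusted p = 5.5e-06, limma) and Abcg1 at -2.15 ± 0.34. Complement genes fell in 4 of 16 cases (7 adjusted over the list alone; adjusted p = 0.471 with an estimated correlation).
In EKO against WT on the same diet and duration, ER stress genes rose in 9 of 16 cases (9 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation), with Sdf2l1, a chaperone partner in the endoplasmic reticulum, at 42.3 ± 3.32 against 6.39 ± 1.73. Complement genes rose in 11 of 16 cases (11 adjusted over the list alone; adjusted p = 0.175 with an estimated correlation), and interferon-stimulated genes in 9 of 25 (10 adjusted over the list alone; adjusted p = 0.671 with an estimated correlation), with the antiviral Oas1a at 2.60 ± 0.43. Neutrophil genes rose in 3 of 11 cases without a list call (3 adjusted over the list alone; adjusted p = 0.793 with an estimated correlation), the granule protein Lcn2 by 4.35 ± 0.64.
For 3 of 7 mast cell genes the diet difference at 22 weeks was more negative in EKO than in WT (4 adjusted over the list alone; adjusted p = 0.142 with an estimated correlation), with the tryptase Tpsb2 at -2.96 ± 0.53 (adjusted p = 0.00099). The 879 genes of this interaction were reached by 6 of 100 groupings, so chance cannot be excluded for their number.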
